A study of Mus musculus with 12 samples.

How the data were processed

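The deposited table held bulk RNA-seq of 12 mouse tumours, 5 from mice given a control injection and 7 from mice given tamoxifen. Per the labels' protocols, RNA was isolated with a column kit and 1.3 ug of total RNA entered a SMARTER mRNA-seq library preparation. Per the submitters' processing notes, the genome build was GRCm38 (mm10). The aligner, the counting tool, the annotation, the read layout and the use of strand are not given in the sources used here. The labels' growth and treatment text describes fat cell differentiation of a mesenchymal cell line, which does not match tumour samples, so groups were taken from the sample titles and the treatment label alone.

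Per the file headers, the authors deposited raw counts per Ensembl gene, which were whole numbers, and rlog values on the log2 scale. The table also carried the authors' own comparison, with a log2 fold change, a signed fold change, an unadjusted p-value and an adjusted p-value per gene, and the test behind them is not given in the sources used here. The rlog values were not tested. Columns were matched to samples by the library name that the labels give for each sample.

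The table had 25116 rows, and no row was 0 in every library. In 248 rows no symbol was given and in 25 rows the symbol had been turned into a calendar date. Symbols for 189 rows were taken from a reference table by Ensembl ID, including all 25 dates, and 84 rows kept the ID alone. Positions, strand, exonic length and GC content came from GENCODE mouse release 21 on GRCm38, in which 25032 of the IDs were found.

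Total counts ranged from 18993192 to 28372821 per library, and 21350 to 24087 genes had at least 1 count. Spearman correlations between libraries ranged from 0.94 to 0.992. The chi-square per gene between libraries of one group was 13 to 220.1 over genes with a mean count of at least 50, so no pair of libraries agreed within sampling noise and each was counted as its own sample.

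Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group with its minimum count of 10, which left 15199 genes and removed 9917. TMM factors were used, and induced was compared with control by the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are induced minus control on the log2 scale, with standard errors from the same fit. Values per library are CPM, counts scaled by library size with TMM factors, and log2 CPM was computed with a prior count of 2. The common biological coefficient of variation was 32.1% and the median standard error of a log2 fold change was 0.183.

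A set of 44 gene lists, the tests of genes, of lists by camera and of Hspg2, the rule for named genes and the alternatives, except those named as added, were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 with the preset inter-gene correlation of 0.01, adjusted over the lists, where at least 3 members were measured. The same lists were tested with the correlation estimated per list and with fry. An exact permutation test of the list score, which is the mean over members of log2 CPM centred on each gene, was added after the data were seen. The exact tests, of list scores and of Hspg2, used all 792 ways of choosing 5 of the 12 libraries, were two-sided and could not give a p below 0.00126. Intervals are 95% intervals of the difference from inverting the permutation test in steps of 0.01. The rule named Hspg2 and the genes past the threshold. Where none passed, it named the 10 genes with the smallest p in each direction among those with a mean log2 CPM over 1 and a symbol that was not a predicted name, as values only. For each list described, up to 4 members with the smallest p could be named.

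The fit was tested on simulated counts with the means and library sizes of these samples. Of 100 genes changed 2-fold, 67 were called, and of 100 changed 4-fold, 86 were called, among 14875 genes tested. No called gene had the wrong sign, and 9 of 14651 unchanged genes were called. An endothelial list simulated 2-fold lower reached an adjusted p of 1.8e-36 with the preset correlation and 3.3e-06 with the estimated one, and 0 of 41 other lists were called. The simulated genes were drawn independently of each other. In the real tumours, the lists that passed with the preset correlation had estimated correlations of 0.11 to 0.84. The simulation therefore does not show how often genes or lists are called where genes vary together.

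Alternatives were other size factors, other filters, no robust estimation, DESeq2 1.42.0, limma-voom with sample quality weights, a block for the replicate number, 1 surrogate variable from sva 3.50.0, and the removal of each library in turn. Added after the data were seen were fits without libraries that stood apart, a term for that split, the exact test of list scores, and corrections for trends with exonic length and GC content (loess span 0.3). Figures were drawn with matplotlib 3.10.9. The lists and the fits describe whole tumour pieces, so a change in the share of a cell type cannot be separated from a change within cells. All tumours of one group differ from the other group in tamoxifen as well as in the induced gene. Some marker genes are not reported here. The mammary gland epithelium list had fewer than 3 measured members and was not tested.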

Results

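Gene expression was measured in tumours of E0771 cells, a mouse triple-negative breast cancer line, grown in the mammary fat pads of syngeneic C57BL/6J mice. The host mice carried Tie2CreER, a tamoxifen-activated recombinase expressed in endothelial cells, and an inducible knock-in gene for endorepellin. Endorepellin is the C-terminal part of perlecan, a heparan sulphate proteoglycan of basement membranes, and is known to bind endothelial receptors and to inhibit angiogenesis. Tamoxifen (7 tumours, called induced) or a control injection (5 tumours, called control) was given before the tumour cells, and tumours were collected at day 22. The comparison asks how endothelial expression of endorepellin affects the tumour transcriptome. Total counts were 18993192 to 28372821 per library.

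Perlecan mRNA, counted to Hspg2, did not differ between the groups beyond the spread of the tumours. Control tumours held 550 ± 81.4 CPM (SD, n = 5) and induced tumours 536 ± 100.2 CPM (SD, n = 7). The lowest value was 420 CPM in induced 6 and the highest 699 CPM in induced 3, and the control tumours ranged from 468 CPM to 659 CPM. Hspg2 (ENSMUSG00000028763) lies on chromosome 4 from 137468769 to 137570630 on the plus strand (GRCm38), with 14307 exonic bases. Its log2 fold change was -0.04 (SE 0.14, adjusted p = 0.99989, edgeR quasi-likelihood test). The difference in log2 CPM was -0.05 with a 95% interval from -0.36 to 0.27 (exact permutation test, two-sided, p = 0.742), which covers fold changes from 0.779 to 1.21. The sign of this fold change depended on single libraries, with 0.04 without control 5, 0.0021 without induced 1 and 0.01 without induced 6. Whether reads of the knock-in gene were counted to Hspg2 is not given in the sources used here, so the value is not a measure of induction.

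**Figure D1:**
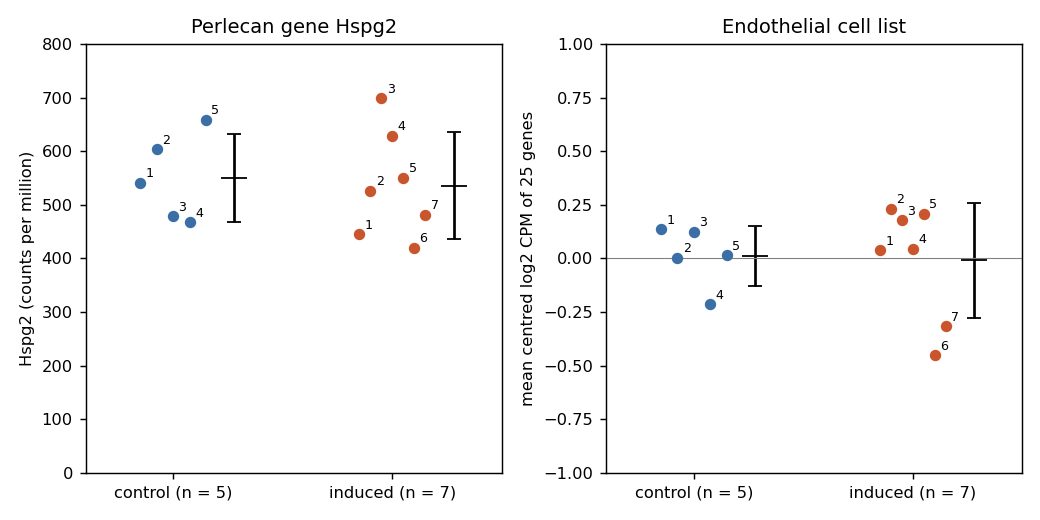
Left, Hspg2 in CPM for each tumour, and right, the score of the endothelial cell list (mean of centred log2 CPM over 25 genes), with the replicate number beside each point and the mean ± SD of each group as a black bar. In both panels the 5 control and 7 induced tumours overlap.

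No single gene passed the threshold between induced and control tumours. Among the genes with the smallest p that were lower in induced tumours, S100a9, a calcium-binding protein of neutrophils, was at 15.8 ± 18.2 CPM in control and 3.31 ± 1.96 CPM in induced tumours, and Ighm, the constant region of the immunoglobulin M heavy chain, at 14.2 ± 12.4 CPM and 3.99 ± 1.59 CPM (SD, n = 5 and n = 7). Bin2, a membrane-bending protein of leukocytes, was at 25.4 ± 5.55 CPM and 17.9 ± 1.48 CPM, and Il16, a cytokine that attracts CD4-positive cells, at 5.44 ± 3.27 CPM and 2.57 ± 0.50 CPM. Among the genes that were higher in induced tumours, Hmga2, an architectural chromatin protein of embryonic and tumour cells, was at 196 ± 31.1 CPM in control and 266 ± 50.7 CPM in induced tumours. Qk, an RNA-binding splicing regulator, was at 147 ± 8.39 CPM and 171 ± 11.8 CPM.

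By edgeR's quasi-likelihood test, 0 of 15199 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.999886. At an unadjusted p under 0.05 there were 324 genes, 90 higher and 234 lower in induced tumours, where 759.95 would be met by chance. DESeq2 and limma-voom also gave 0 genes at the threshold, with 607 and 1134 genes at an unadjusted p under 0.05. In the authors' deposited table, 0 of 24894 genes had an adjusted p under 0.05, with a smallest value of 0.485 for Abi3, and 632 genes had an unadjusted p under 0.05, of which 153 were higher and 479 lower. The sign of the fold change in the authors' deposited table was the same as in the edgeR fit for 99.36% of 11958 genes with a mean log2 CPM over 1. The authors' fold changes lay within 0.05 log2 of the DESeq2 fit for 100% of the rows compared. All of these fits use the same counts, so their agreement is not separate support.

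The 10 named genes with lower values were Abi3 (log2 fold change -1.32, SE 0.30), Bin2 (-0.51, SE 0.13), Ifitm1 (-1.47, SE 0.39), Gngt2 (-0.99, SE 0.26), Il16 (-1.08, SE 0.29), Pced1a (-0.33, SE 0.09), S100a9 (-2.25, SE 0.63), Lcn2 (-2.61, SE 0.74), Ighm (-1.84, SE 0.53) and Mmp9 (-3.02, SE 0.89). The smallest unadjusted p was that of Abi3, a regulator of actin, at 0.000746. The 10 with higher values were Hmga2 (0.45, SE 0.14), Ttbk2 (0.35, SE 0.11), Qk (0.22, SE 0.07), Rras2 (0.31, SE 0.10), Zfp9 (0.32, SE 0.11), Arvcf (0.50, SE 0.17), mt-Tp (0.84, SE 0.30), Smap1 (0.31, SE 0.11), Rab27b (0.73, SE 0.26) and Nus1 (0.25, SE 0.09). Each of these 20 genes had an adjusted p of 0.99989 in the edgeR fit. For 19 of them all 7 induced tumours lay on that side of the control mean, and for Rab27b 6 of 7 did. As the genes were picked for the smallest p in each direction, this was likely beforehand and is no separate support. The 2 groups did not overlap for Bin2, Il16, Pced1a and Qk. Over all genes tested, 9 had groups that did not overlap, a share of 0.0592% where chance gives 0.2525%.

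Abi3 lies on chromosome 11 from 95830074 to 95842476 on the minus strand, Bin2 on chromosome 15 from 100641077 to 100669553 on the minus strand, Il16 on chromosome 7 from 83642825 to 83745726 on the minus strand, Hmga2 on chromosome 10 from 120361275 to 120476469 on the minus strand and Qk on chromosome 17 from 10202601 to 10319854 on the minus strand (GRCm38). Counts of some named genes are uncertain because they share exonic bases with other genes. Neither the use of strand nor the counting tool is given. Of the exonic bases of Abi3, 70.1% also lie in exons annotated to Zfp652, 41.1% in exons of Phospho1 and 5.63% in exons of Gngt2, all on the opposite strand. Smap1 shares 58.1% of its exonic bases with B3gat2 on the opposite strand, Ttbk2 29.9% with Cdan1 on the same strand, and Il16 15.3% with Stard5 on the opposite strand. The mitochondrial tRNA gene mt-Tp is short and is transcribed as part of a long precursor. Single control tumours carried part of the lower values. Without control 2 the log2 fold change was -0.67 for Mmp9, -0.93 for Lcn2 and -1.26 for S100a9, and without control 1 it was -0.64 for Il16.

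The vessel-related lists, which are closest to the question of the study, had score differences near 0. Of 25 endothelial genes measured, 10 were higher and 15 lower in induced tumours, and none passed the test over all genes or adjusted over the list alone. Ecscr, an endothelial surface protein, was at 11 ± 1.89 CPM in control and 8.07 ± 1.67 CPM in induced tumours, Flt1, a receptor for VEGF-A, at 13.2 ± 1.20 CPM and 16.1 ± 2.82 CPM, and Eng, a TGF-beta co-receptor, at 130 ± 13.7 CPM and 118 ± 11.6 CPM (SD, n = 5 and n = 7). The endothelial score differed by -0.02 (95% interval -0.33 to 0.26, exact permutation test, p = 0.875). Sprouting and angiogenic factors were split into 11 higher and 11 lower, with Pgf, a VEGF family growth factor, at 8.09 ± 2.40 CPM and 10.9 ± 3.02 CPM and Jag1, a Notch ligand, at 25.5 ± 5.45 CPM and 29.7 ± 2.31 CPM. Their score differed by -0.03 (95% interval -0.25 to 0.18). The differences were -0.05 for pericytes and smooth muscle (interval -0.58 to 0.53), -0.03 for lymphatic endothelium (-0.86 to 0.78), -0.09 for angiostatic factors (-0.73 to 0.52) and 0.06 for the 3 measured endorepellin receptors (-0.24 to 0.35). These 3 were Flt1, Kdr and Itgb1. The integrin gene Itga2, also on that list, was not among the genes tested, so the score does not cover it. Kdr, the main VEGF receptor of endothelial cells, was at 16.5 ± 4.50 CPM in control and 15.8 ± 5.18 CPM in induced tumours.

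The basement membrane, hyaluronan, autophagy and matrix protease lists had score differences from -0.19 to -0.04. The basement membrane list had 4 members higher and 13 lower, with a score difference of -0.05 (95% interval -0.47 to 0.35). The hyaluronan list had 8 higher and 7 lower, with a difference of -0.08 (interval -0.42 to 0.19). Its member Cd44, the main cell-surface receptor for hyaluronan, was at 474 ± 41.7 CPM in control and 546 ± 62.6 CPM in induced tumours (SD, n = 5 and n = 7), and Has2, a hyaluronan synthase, did not pass the filter on low counts. Autophagy and lysosome genes had 11 higher and 21 lower, with a difference of -0.04 (interval -0.18 to 0.10), and Tfeb, a transcription factor for lysosomal genes, was at 4.65 ± 1.79 CPM and 3.25 ± 0.66 CPM. Among matrix proteases, 7 were higher and 13 lower, with a difference of -0.19 (interval -0.71 to 0.28). Mmp12, the macrophage elastase, was higher in induced tumours, at 29.8 ± 16.5 CPM against 14.5 ± 6.86 CPM. Mmp9, a gelatinase, was lower, at 1.64 ± 1.20 CPM against 13.4 ± 24.1 CPM, as were Ctsk, a collagen-degrading cathepsin, at 3.64 ± 3.10 CPM against 16.2 ± 21.4 CPM and Mmp3 at 3.96 ± 0.99 CPM against 8.60 ± 9.60 CPM. None of the members of these lists passed the threshold adjusted over the list alone, although Mmp9 did over the neutrophil list, and its log2 fold change of -3.02 was -0.67 without control 2. None of the vessel, matrix or autophagy lists in this and the preceding comparison passed the preset-correlation test.

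Neutrophil and B cell genes were lower in induced tumours as groups, but no list held once the correlation between genes was estimated. Of 15 neutrophil genes measured, 13 were lower and 2 higher. None passed over all genes and 8 passed adjusted over the list alone, among them S100a9, S100a8, Mmp9 and Cxcr2, the neutrophil chemokine receptor, which was at 1.67 ± 1.59 CPM in control and 0.35 ± 0.14 CPM in induced tumours (SD, n = 5 and n = 7). Of 11 B and plasma cell genes, 10 were lower, none passed over all genes and 3 passed adjusted over the list alone, Ighm, Fcrla and Igkc. The immunoglobulin kappa constant region Igkc was at 7.77 ± 10.5 CPM and 1.17 ± 1.06 CPM. The neutrophil score differed by -0.92 (95% interval -1.95 to 0.10, exact permutation test, p = 0.0758) and the B and plasma cell score by -0.84 (interval -1.91 to 0.30, p = 0.129). With the preset correlation the adjusted camera p was 3.32e-09 for neutrophils and 4.33e-06 for B and plasma cells. For both it was adjusted p = 0.815 with an estimated correlation. The neutrophil difference rested on control 1 and control 2, since without both it was -0.20 with a preset-correlation adjusted p of 0.517. For B and plasma cells it was then -1.17 with a preset-correlation adjusted p of 4.16e-08. That fit kept control 4 and control 5, with B and plasma cell scores of 1.55 and 1.49, and a fit without both of these was not run. Within control 1, control 2, induced 3 and induced 4 alone, the B and plasma cell difference was -0.23 (preset-correlation adjusted p = 0.890). Over all alternatives the adjusted p ranged from 3.13e-13 to 0.991 for neutrophils and from 4.28e-11 to 0.991 for B and plasma cells.

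**Figure D2:**
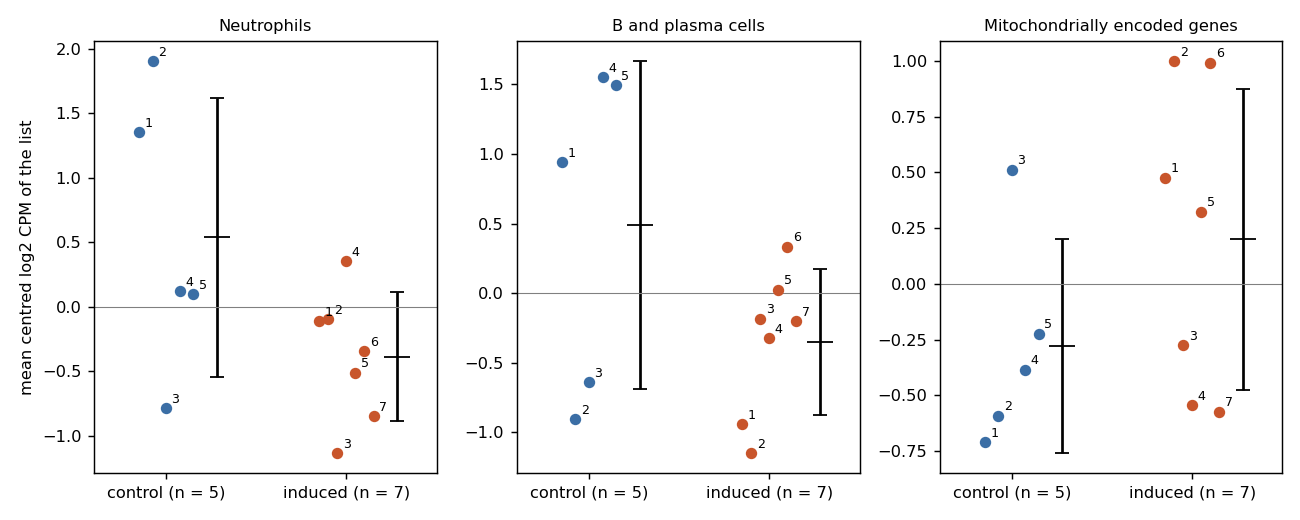
Score per tumour (mean of centred log2 CPM over the list) for neutrophils, B and plasma cells and mitochondrially encoded genes, with the replicate number beside each point and the mean ± SD of each group as a black bar. Control 1 and control 2 hold the highest neutrophil scores, and control 1, control 4 and control 5 the highest B and plasma cell scores.

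Other immune and stromal lists were lower in induced tumours, with wide intervals. All 9 MHC class II genes were lower, with H2-Aa, an antigen-presenting alpha chain, at 41.1 ± 54.2 CPM in control and 18.5 ± 8.65 CPM in induced tumours, and 12 of 13 T cell genes were lower, with Foxp3, the regulatory T cell factor, at 1.06 ± 1.14 CPM and 0.39 ± 0.20 CPM (SD, n = 5 and n = 7). Of 23 macrophage and monocyte genes 19 were lower, as were 15 of 15 complement genes, 24 of 29 interferon gamma response genes, 27 of 32 type I interferon response genes, 18 of 20 inflammatory cytokine and chemokine genes, 9 of 9 checkpoint genes, 11 of 12 dendritic cell genes and 20 of 26 fibroblast and fibrillar matrix genes. The chemoattractant receptor Cx3cr1 was at 1.35 ± 1.31 CPM and 0.22 ± 0.24 CPM, the cytokine Il1b at 23.7 ± 17.7 CPM and 9.04 ± 4.21 CPM, and the complement component C3 at 41.6 ± 46.9 CPM and 16.7 ± 14.8 CPM. None of these genes passed over all genes or adjusted over any of these lists alone, although Il1b, which is also in the neutrophil list, passed adjusted over that list (adjusted p = 0.0273). Score differences ranged from -0.61 for MHC class II to -0.11 for the type I interferon response, with 95% intervals of -1.68 to 0.41 and -0.34 to 0.11. These 10 lists passed the preset-correlation test, and for them the adjusted p was 0.815 to 0.826 with an estimated correlation. These calls depended on single tumours. Without control 1, whose tumour had the highest fibroblast, T cell, macrophage, complement and MHC class II scores, only inflammatory cytokines and chemokines still passed among these 10 lists with the preset correlation (adjusted p = 0.0164), and this list did not pass without control 2 (adjusted p = 0.171). Without control 1 the difference was -0.19 for MHC class II and -0.03 for the type I interferon response, and it turned to 0.02 for complement, 0.02 for macrophages and monocytes and 0.04 for fibroblasts. Further calls ended without control 3 (T cells 0.0627, dendritic cells 0.134), induced 3 (type I interferon 0.0536, dendritic cells 0.335), induced 4 (dendritic cells 0.0616), induced 6 (macrophages 0.0554, fibroblasts 0.0595) and induced 7 (macrophages and fibroblasts 0.0865, checkpoints 0.0531, dendritic cells 0.112), given as adjusted p.

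Mitochondrially encoded, cell cycle and skeletal muscle genes passed as lists with the preset correlation but not with an estimated one. All 13 mitochondrially encoded genes were higher in induced tumours, with mt-Cytb at 2452 ± 923.7 CPM in control and 3597 ± 1650 CPM in induced tumours (SD, n = 5 and n = 7), and 25 of 31 cell cycle genes were lower, with Mcm7, a part of the replicative helicase, at 118 ± 7.17 CPM and 103 ± 13.2 CPM. The scores differed by 0.48 (95% interval -0.32 to 1.30) and -0.08 (interval -0.21 to 0.03). Skeletal muscle genes, a sign of muscle in the sampled piece, were higher for 11 of 19 members, with a difference of 0.77 (interval -1.57 to 3.04) and Neb at 5.60 ± 4.57 CPM and 8.60 ± 5.62 CPM. The muscle difference was 0.09 without control 1, 0.54 without control 3 and 0.35 without induced 4, where the list no longer passed with the preset correlation (adjusted p of 0.803, 0.0918 and 0.344), and 1.58 without control 4. No member of the 3 lists passed over all genes or adjusted over the list alone. The lists passed the preset-correlation test with adjusted p of 4.33e-06, 0.00249 and 0.00191, and the adjusted p was 0.815 for mitochondrially encoded genes and cell cycle and 0.826 for skeletal muscle with an estimated correlation. Without control 1 and control 2, none of the 3 lists passed with the preset correlation.

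In all, 15 of 43 lists passed camera with the preset correlation, 13 lower and 2 higher in induced tumours. With an estimated correlation 0 passed, and only neutrophils had an unadjusted p under 0.05 (p = 0.0404). By fry 0 passed, with a smallest adjusted p of 0.991, and by the exact permutation test 0 passed, with a smallest adjusted p of 0.964. The other 28 lists had adjusted p of 0.0733 to 0.989 with the preset correlation. Besides those above, their score differences were -0.13 for MHC class I presentation, -0.14 for cytotoxic and NK cells, 0.13 for mast cells, 0.22 for carcinoma epithelium, 0.06 for EMT and mesenchymal genes, -0.28 for adipocytes, -0.29 for skin keratinocytes, -0.15 for erythrocytes, -0.00037 for platelets and clotting and -0.21 for nerve and Schwann cells. They were -0.03 for hypoxia and glycolysis, -0.01 for oxidative phosphorylation, -0.02 for the unfolded protein and integrated stress response, -0.04 for estrogen response, -0.01 for Wnt and Notch targets, 0.04 for cytosolic ribosomal proteins, -0.03 for immediate early genes and -0.10 for heat shock. The estrogen response list was read because tamoxifen acts on estrogen receptors. The median fold change, the score difference and the test differed in sign for 10 lists, none of them among the 15: Wnt and Notch targets, lymphatic endothelium, sprouting and angiogenic factors, unfolded protein and integrated stress response, mast cells, immediate early genes, platelets and clotting, estrogen response, hyaluronan and erythrocytes.

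**Figure D3:**
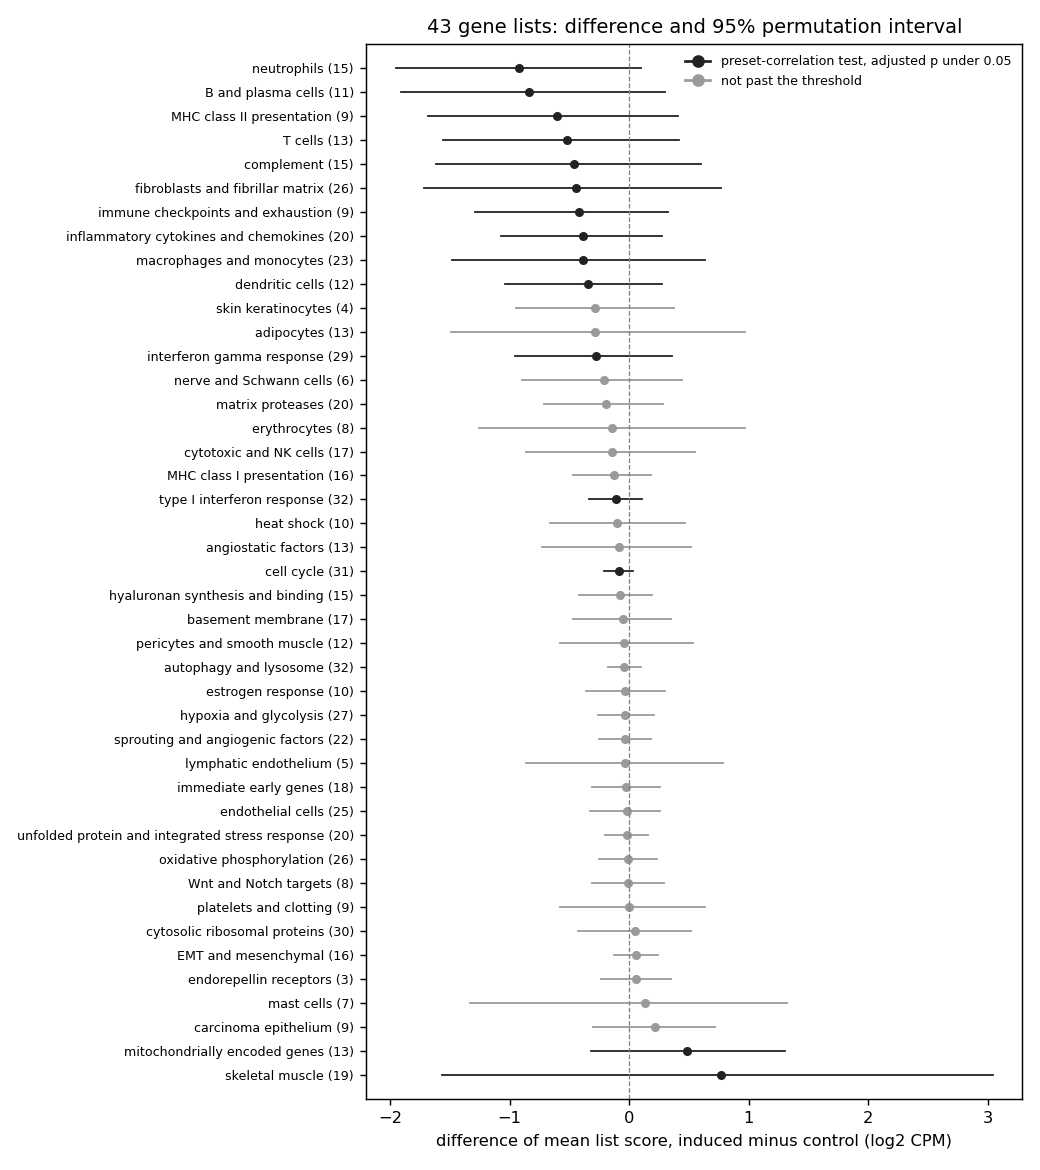
Difference of the mean list score, induced minus control, on the log2 CPM scale (points) with its 95% permutation interval (lines) for 43 lists, with the number of measured genes in parentheses. Black marks the 15 lists past the preset-correlation test, and all 43 intervals include 0.

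The tumours did not separate by group. The first principal component of the 500 most variable genes held 52.9% of the variance and set control 1, control 2, induced 3 and induced 4 (scores of -44.0, -26.4, -20.4 and -37.9) apart from the other 8 tumours (4.15 to 22.5). These 4 libraries also had a positive trend of expression with gene length, from 0.109 to 0.134 log2 per doubling of exonic length, where the other 8 had -0.0950 to -0.0128. No label names a batch that matches this split. The library names of control 1 and control 2 carry adjacent numbers, as do those of induced 3 and induced 4. Whether the order of the names reflects handling is not given, and it was not tested. Within the other 8 tumours, 0 genes passed and 7 lists passed with the preset correlation, and within the 4 tumours 0 genes and 19 lists did. With a term for the split, 0 genes and 13 lists passed.

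**Figure D4:**
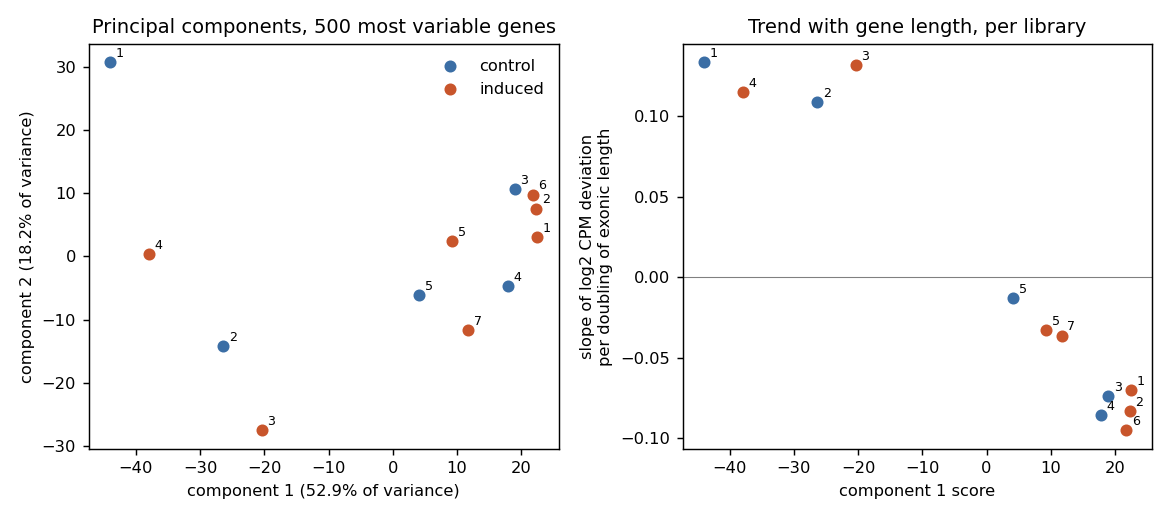
Left, the first against the second principal component of log2 CPM for each tumour, and right, the slope of log2 CPM deviation per doubling of exonic length against the first component, with the replicate number beside each point. Control 1, control 2, induced 3 and induced 4 sit apart on the first component and have slopes above 0.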

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

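Tests of library depth, host tissue, blood, immune cells of every kind and lymph node tissue, and the split count for genes past the threshold, were chosen after the result was seen. In control tumours, 1 value lay far from the others for Il16 (gap over range 0.758, control 1), Hmga2 (0.787, control 2), Ccr7 (0.857, control 1), C1s1 (0.772, control 1), Dcn (0.719, control 1), Xirp2 (0.737, control 1), Neb (0.732, control 4), Myc (0.808, control 1), H2-Aa (0.727, control 1) and Flt4 (0.737, control 3). In induced tumours this held for Ifi27l2a (0.622, induced 3), Cd44 (0.793, induced 4), Ctsk (0.59, induced 4), Gzmf (0.571, induced 3), Gzmg (0.59, induced 3), Col12a1 (0.579, induced 4) and Thbs2 (0.596, induced 4). Among list scores it held in control 1 for lymphatic endothelium (0.733), dendritic cells (0.835), mast cells (0.764), immune checkpoints (0.759) and nerve and Schwann cells (0.854), and in induced 4 for fibroblasts (0.649) and complement (0.611). Of 278 groups of values checked, 24 had such a tumour, and 12 of the 24 were in control 1. Chance gives about 13.9 for values that were not picked by their size. Some of these genes were picked for a small p or for a tumour that stood out, and the lists share members with them. The excess over chance therefore decides nothing.

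The first pattern is that control 1, control 2, induced 3 and induced 4 lay apart from the other 8 tumours on the first component. All 4 length slopes lay beyond those of the other 8, yet after each library's length trend was removed the gap kept 0.876 of its size, which argues against that trend as the whole cause. After removal of the GC trend the gap kept 1 of its size, all 4 totals lay within the range of the other 8, so depth is not the cause, and 4 of 5 lists for host tissue had at least 1 of the 4 tumours below the median of the other 8. For 2 of these lists, T cells and MHC class II, this was by more than the SD of the other 8. This held in induced 3 for both and in control 2 for MHC class II. These values argue against more T cells or more cells with MHC class II as a cause shared by all 4. They do not argue against host tissue as a whole. The fibroblast list had 0 of the 4 below that median, with scores from -0.09 to 2.22 against a median of -0.46. Control 1 (2.22) and induced 4 (1.58) were far above it and control 2 was at 0.27. Induced 3 (-0.09) was close to induced 5 (-0.10), which is among the other 8. More fibroblast tissue in the 4 stays open. A difference in RNA quality or preparation could remain as a source, since no label gives a batch. The split crosses the groups, and no biological explanation other than host tissue was tested.

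The second pattern is the lower neutrophil list in induced tumours, carried by control 1 and control 2 with scores of 1.35 and 1.91. Blood left in the tumours stays open. Blood as the source predicted the 2 highest erythrocyte scores in control 1 and control 2, which did not hold. Their erythrocyte scores were -0.08 and 0.30. The 2 highest were 1.68 in induced 5 and 0.55 in induced 3, whose neutrophil scores were -0.51 and -1.13. The erythrocyte score was below the median of the 12 tumours in 1 of these 2 control tumours, control 1, but in 0 of 2 by more than the SD of the other 10 tumours. More immune cells of every kind in control 1 and control 2 stays open too. Control 2 was below the median for 3 of 4 lists (T cells, B and plasma cells and MHC class II), but for 1 of 4, MHC class II, by more than that SD, and this is a single tumour. A neutrophil-rich reaction in those tumours was not tested. A difference by treatment was tested in the comparison of the groups, where the list did not pass with an estimated correlation (adjusted p = 0.815) or in the exact test (p = 0.0758), and it stays open.

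The third pattern is the high B and plasma cell list in control 1, control 4 and control 5, for which lymph node tissue in those tumour samples is a candidate source that stays open. The mean score of 4 measured lymph node markers of 10 listed, 1 of which (Ccr7) also stands in the dendritic cell list, was higher in 3 of the 3 than in each of the other 9 tumours. B cells themselves express Cr2 and Fcer2a, so this score does not separate node tissue from B cells within the tumours. The markers above the range of the other 9 differed between the 3 tumours. In control 1, Ccr7, Ighm and Igkc were above it, at 11.7, 33.3 and 26.0 CPM, as was the T cell score of 2.07, and Cxcl13 had 106 counts against at most 22 in every other tumour, while Cr2, Fcer2a and Ms4a1 were within it. In control 4 and control 5, Cr2 was above it, at 11 and 9.66 CPM against at most 2.12 CPM, as were Fcer2a, Ms4a1, Ighm and Igkc, while Ccr7 and the T cell score were not. A difference by treatment was tested in the comparison of the groups, where the list did not pass with an estimated correlation (adjusted p = 0.815) or in the exact test (p = 0.129), and it stays open.

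Chance cannot be excluded for the 324 genes at an unadjusted p under 0.05 or the 15 lists of the comparison between induced and control tumours. Over 100 splits of the 12 tumours into groups of 5 and 7, drawn from 792 and with the real one included, all 100 gave at least the 0 genes of the real split at the adjusted threshold, which any split does and which decides nothing, and the highest other split gave 3877. For genes at an unadjusted p under 0.05, 74 of the 100 gave at least the real 324, and the highest other gave 6197. For lists with the preset correlation, 42 of the 100 gave at least the real 15, and the highest other gave 26. The split with the most genes put control 1, control 2, induced 1, induced 3 and induced 4 together, which points to a structure of the samples that the groups do not follow.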

How the results depend on the processing

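Fits without control 1 and control 2 or without the 4 tumours that stood apart, within those 4, with a term for that split, with length or GC trends removed, and the exact test of list scores were chosen after the data were seen. The count of genes past the threshold was 0 in the fit reported and in every alternative, including each tumour left out in turn (0 to 0). At an unadjusted p under 0.05 it ranged from 105 with the replicate block to 1134 with limma-voom, and from 198 without control 1 to 745 without induced 4. The 20 named genes kept their sign in all 540 combinations of gene and alternative, and none passed. They were picked for a small p in the same tumours, so a kept sign was likely beforehand and is no separate support. Hspg2 had a log2 fold change from -0.1142 to 0.0371 as each tumour was left out, with positive values without control 5 (0.0371), induced 1 (0.0021) and induced 6 (0.0132). It was also positive with the replicate block (0.0367), with 1 surrogate variable (0.012) and within the 4 tumours (0.205). The replicate numbers do not pair the tumours, with correlations of same-numbered deviations from -0.531 to 0.21 and 0 of 5 best matched with their own number, and with the replicate block 15 lists passed, 11 of them among the 15 reported. Against 15 lists, 8 passed with limma-voom (5 of them among the 15), 7 without the 4 tumours (4 among them), 4 without control 1 and control 2 (1 among them), and 0 with an estimated correlation, 0 with fry and 0 with the exact permutation test. As each tumour was left out the count ranged from 7 (without control 1) to 17, and score differences ranged from -0.694 to 0.0177 for complement, -0.6099 to 0.0248 for macrophages and -0.7414 to 0.0369 for fibroblasts. Of 420 combinations of these lists and alternatives, 296 kept direction and call, 112 kept the direction alone and 12 reversed. The 3 upper values were those without control 1. Without the 4 tumours they turned to 0.0327 for the interferon gamma response, 0.1388 for inflammatory cytokines, -0.7909 for skeletal muscle and 0.0104 for macrophages. Without control 1 and control 2 they turned to 0.0471 for inflammatory cytokines, 0.1836 for complement, -0.1546 for skeletal muscle, 0.2248 for macrophages and 0.2045 for fibroblasts. With an estimated correlation only the allowance for correlation among members differed. Without tumours the filter on low counts was applied anew, so the genes tested and, in some of these fits, the lists tested differed too. Fry and the permutation test also drop the comparison with other genes, and the cause of these and the other changes was not tested. Within the 4 tumours 19 lists passed with the preset correlation, 11 of them among the 15 reported. Depth limits the comparison for the 9917 rows below the filter on low counts.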

Other observations

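All values in this part were singled out after the data were seen. Induced 3 held a high level of a granzyme cluster, serine proteases of cytotoxic lymphocytes. Gzmd was at 60.9 CPM, Gzme at 28.1 CPM, Gzmf at 95.8 CPM and Gzmg at 73.1 CPM in this tumour, while no other tumour exceeded 12.2 CPM for Gzmd, 5.46 CPM for Gzme, 10.6 CPM for Gzmf and 5.04 CPM for Gzmg. These genes are near-identical copies, so counts between them are uncertain. The T cell score of the same tumour was -0.77, below that of each control tumour.

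Some stromal genes had their highest values in control 1 and induced 4. Lum, a small proteoglycan of collagen fibrils, was at 75.9 CPM in control 1 and 10.0 CPM in induced 4 and at most 2.69 CPM elsewhere, and Col12a1, a fibril-associated collagen, was at 102 CPM and 35.6 CPM and at most 10.2 CPM elsewhere. The same tumours had the most counts of Xist, the RNA of the inactive X chromosome, with 5765 and 2102 and at most 1391 elsewhere. Has2, a hyaluronan synthase, had 84 counts in control 1 and 23 in induced 4, and at most 11 elsewhere. Acta1, the actin of skeletal muscle, ranged from 0.484 CPM in control 1 to 178 CPM in induced 4. Vim, an intermediate filament of mesenchymal cells, was at 3884 CPM or more in all 12 tumours, while Krt8, an epithelial keratin, stayed at or below 2.29 CPM.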
